A study of Arabidopsis thaliana with 6 samples.

How the data were processed

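Gene expression was measured in 6 samples of Arabidopsis thaliana shoot apical meristem and juvenile leaves, each total RNA of 30 pooled plants and each hybridised to 1 array. Per the labels' protocols, cDNA was labelled with the green dye Alexa 555, so each array has 1 colour. The intensity values come from scanner files deposited by the authors, which per the file headers were made with Agilent Feature Extraction on a design of 4 arrays per slide; its version, 10.5.1.1, is from the submitters' processing notes. In those files the authors' processed intensity of a spot is, per the file headers, background-subtracted with spatial detrending within the array and not scaled between arrays. The deposited files also hold the median intensity of each spot and its local background, and flags of 0 or 1 for spots well above background, saturated or outlying. A deposited table of the authors holds log2 values per probe without a statement of scale. Set against the scanner values, 99.9% of its 43603 probes on each array lay within 0.01 of 1 constant offset from the log2 processed intensity minus the 75th percentile of the array, so scale, centring and direction are known and the table nearly repeats the main scale. Its column medians were -2.079 (0 h), -2.116 (1 h), -2.142 (3 h), -2.108 (6 h), -2.079 (XVE) and -2.136 (DMSO).

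For the main values, log2 of the processed intensity minus the 75th percentile of the array was taken over 43803 non-control spots. Spots of the same probe were averaged with outlier-flagged spots left out. A probe without an unflagged spot on every array (139 of 43603) was not used. Probes were named through unversioned RefSeq accessions in a gene table of the TAIR10.1 assembly, used for names and gene order only: 34285 probes matched 1 locus, 9318 none and 0 several. A gene was the mean of its probes well above background on at least 1 array, which gave 21297 genes, 5950 of them with several probes and 17995 well above background on all 6 arrays. A gene counted as well above background on an array if at least 1 of its probes was. The mean of a gene with several probes can therefore include dim probes and lie below the lowest signal well above background. No spot was saturated.

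Samples were grouped by the source names in the labels, and 8 comparisons were fixed, with the gene lists and the rule for named genes, before the data were examined. With 1 array per group there are no replicates and no residual degrees of freedom, so no test was made: genes at least 2-fold apart were counted among those well above background on every array compared. Against all 3 controls (untreated, DMSO and XVE with estradiol) a gene had to pass 2-fold against each, and its value is the difference of smallest size. A gene well above background on one side only is given as "at least N-fold", the bright value against the higher of the dim value and the lowest signal well above background on that array; against all 3 controls the nearest control sets the bound. The genes named are the 15 farthest in each direction against all 3 controls, the 10 farthest at 1 h and at 3 h, the 5 farthest in the other comparisons, the 3 largest bounds per direction, and up to 4 members of each list per comparison, those with the largest differences; AMY3, reference genes and other list members could be named whatever their values.

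The 29 lists hold 394 genes for hormones, stress, clock, cell cycle, organs, cell types and reference genes, of which 3 (TCH3, HSFB1 and ACT2) had no named probe. A list with at least 5 measured members is described by its median difference and by the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean expression; this describes these arrays and is no test. Lists for the XVE array against 0 h were added after the data were seen.

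The computation was tested on simulated data for the same genes, with noise resampled from the difference between the XVE and DMSO arrays, which lie on 1 slide, so the noise includes any effect of line and estradiol and leaves out slides. Of genes raised 2.5-fold, 4-fold and 8-fold on the 6 h array, 58.5%, 97.2% and 99.8% were recovered against all 3 controls, and 80.3%, 99.1% and 100% against DMSO, among 17995 genes with 200 changed. Of 200 unchanged lists of 15 genes, 4.0% fell beyond the 2.5th or 97.5th percentile, and 98.0% of 50 lists shifted by 0.5 exceeded the 97.5th. The same noise gave the counts that 100 simulations of unchanged arrays reach by chance.

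Alternatives were quantile scaling, cyclic loess, the normexp background correction with an offset of 50, the authors' table, no filter on dim probes, genes well above background on all 6 arrays only, the brightest probe per gene, and leaving out each control. The normexp correction was planned on mean signals; the files used hold no such column, so median spot and background signals were used. Leaving out genes that part the 2 slides was added after the data were seen. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. The signal at the 75th percentile was between 8.99 (XVE) and 38.8 (3 h) times the median local background, so weak genes are measured less well on the XVE array. Slide and scan coincide, and the untreated, 1 h, 3 h and 6 h arrays share slide 1, so the DMSO and XVE arrays cannot be told apart from slide 2. Beyond gene order, no genome positions were used here.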

Results

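RNA from the shoot apical meristem and juvenile leaves of 21-day-old Arabidopsis thaliana plants was measured on 6 single-colour oligonucleotide arrays, with material of 30 plants pooled for each array. The plants carried XVE, a chimeric transcription activator that switches on a target promoter when the steroid 17-β-estradiol is applied. In 5 of the 6 samples they also carried an inducible construct named AMY3C-EY, whose product the labels do not describe. A solution of 20 µM estradiol was brushed onto the meristems of AMY3C-EY plants, which were harvested 1, 3 or 6 h later, and untreated plants stood for 0 h. The controls at 6 h were AMY3C-EY plants brushed with the solvent DMSO and plants with XVE alone brushed with estradiol. Each of the 6 groups was 1 array, so no difference below has a replicate check, no test was possible, and the number of arrays limits the precision. The time course (0, 1, 3 and 6 h) lay on 1 slide and the DMSO and XVE arrays on another, so every comparison between those sets of arrays also compares slides. The 75th percentile of the processed signal was 555.1 at 0 h, 481.8 at 1 h, 1435.4 at 3 h, 810.9 at 6 h, 341.6 on the XVE array and 904.7 on the DMSO array, and between 67.9% and 77.5% of the spots were well above background. Levels below are log2 signals relative to the 75th percentile of the array, and differences are between such levels.

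The question the design puts to the 6 h array is which transcripts differ once the untreated state, the solvent and estradiol itself are set aside. CRC, a YABBY transcription factor of carpel and nectary development, stood farthest above the controls: its level was 0.36 at 6 h of estradiol, against -1.94 at 0 h, -2.35 with DMSO and -3.45 on the XVE array, a smallest difference of 2.30. JMJD5, a jumonji-domain protein tied to the circadian clock, was at 0.83 against -0.86, -1.42 and -1.62 in the same order. AMY3, which encodes a plastid α-amylase, was at 3.88 against 1.34, 2.53 and 2.47, a smallest difference of 1.35, and it was at 2.49 at 1 h and 3.55 at 3 h. The phosphate transporter gene PHT1;7 (smallest difference 1.37), the sulfate transporter family gene SULTR3;2 (1.47), LAP5, a pollen wall polyketide synthase gene (1.31), UGT72E2, a monolignol glucosyltransferase gene (1.15), and EMB2730 (1.22) were also higher than on all 3 controls. The remaining genes among the 15 farthest above were AT5G26840 (1.99), AT2G22345 (1.63), AT5G56880 (1.56), AT4G08895 (1.26), AT3G03580 (1.24), AT1G51530 (1.18) and AT2G29860 (1.14). CRC, AT5G26840, SULTR3;2, AT3G03580 and EMB2730 were higher on all 4 arrays of slide 1 than on both of slide 2, by less than 2-fold. Under the normexp background correction SULTR3;2 and AT5G56880 were at 0.00, AT4G08895 at 0.60, AT5G26840 at 0.82 and AT3G03580 at 0.88, below 2-fold, and SULTR3;2 was at 0.18 when only the brightest probe was used. On the 3 controls SULTR3;2 lay between -5.10 and -5.01 and AT5G56880 between -5.25 and -4.74. These means of several probes are below the lowest signal well above background there, -4.34 (0 h), -4.56 (DMSO) and -4.09 (XVE). Both differences are thus from dim values.

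On the lower side, the B-box factor gene BBX28 was at -1.65 at 6 h of estradiol, against 0.08 at 0 h, 0.10 with DMSO and 0.43 on the XVE array, a smallest difference of -1.73. RAV2, a repressor of flowering, was lower by a smallest difference of -1.41, PUB22, a ubiquitin ligase gene of the immune response, by -1.50, and the transcription factor gene WRKY41 by -1.14. AT1G33760 (-1.72), AT1G22690 (-1.62), AT2G25735 (-1.37), AT3G44400 (-1.22), AT5G35480 (-1.19) and AT2G17660 (-1.14) were also lower. APPR6 (-1.33), AT2G14160 (-1.32), SNF7.2 (-1.26), BGLU13 (-1.18) and AT1G72910 (-1.16) were at least 2-fold lower than at 0 h on the 1 h and 3 h arrays too. All of these were lower on the 4 arrays of slide 1 than on both of slide 2, APPR6 and AT2G14160 by at least 2-fold, so their differences from DMSO and XVE are also slide differences. SNF7.2, for example, was at 3.01 at 1 h, 2.68 at 3 h and 3.11 at 6 h, against 4.37 at 0 h and 4.67 and 4.66 on the XVE and DMSO arrays. Among genes dim on the 6 h array, AT2G43580 was at least 2.66-fold, AT4G15670 at least 2.52-fold and AT3G01325 at least 2.42-fold lower than on all 3 controls. AT1G77830, AT4G29548 and AT3G51020, dim on all 3 controls, were at least 1.93-fold, 1.89-fold and 1.80-fold higher. Under normexp PUB22 (-0.54), AT2G17660 (-0.82), AT2G25735 (-0.84), AT3G44400 (-0.87), AT1G22690 (-0.90), AT1G33760 (-0.96), AT1G72910 (-0.96) and WRKY41 (-0.97) were less than 2-fold lower. With only the brightest probe PUB22 was at -0.24 and AT2G17660 at -0.91.

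In all, 24 genes were at least 2-fold higher and 33 at least 2-fold lower than on all 3 controls, among 18192 genes well above background on the 4 arrays; CRC alone passed 4-fold, and under normexp it did not (1.86). Arrays simulated without any change, with the spread between the XVE and DMSO arrays, gave a mean of 61.4 higher and 60.8 lower genes, against 24 and 31 observed among the same 17995 genes. In those simulations a mean of 1.89 genes lay as far above the controls as CRC and 21.8 as far as AMY3, where 1 and 8 were observed. Leaving out 1 control raised the counts, to 126 higher and 238 lower without the 0 h array, 54 and 91 without the DMSO array, and 53 and 68 without the XVE array. Without the 0 h array both remaining controls lay on slide 2, so those counts are wholly across slides. With the normexp background correction the counts were 12 and 9, which turns the balance of higher over lower, and without the filter on dim probes they were 99 and 142.

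**Figure D1:**
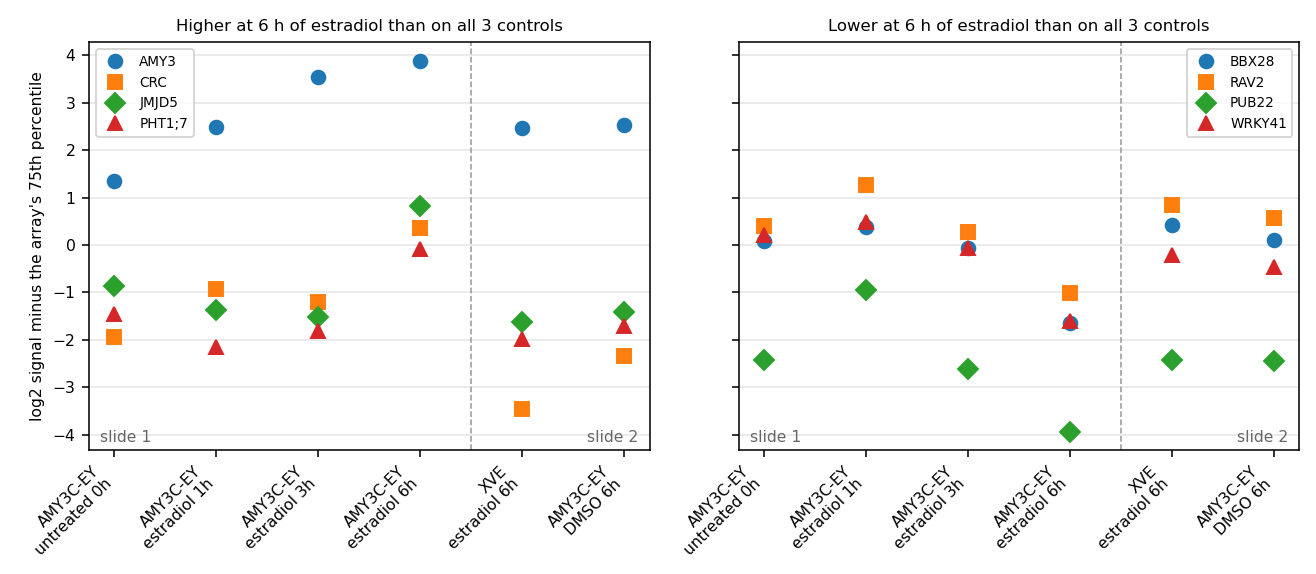
Levels of 8 genes on the 6 arrays, as log2 signal minus the 75th percentile of the array, with 1 point per gene and array, and a dashed line between the arrays of slide 1 and slide 2. AMY3, CRC, JMJD5 and PHT1;7 are highest at 6 h of estradiol, and BBX28, RAV2, PUB22 and WRKY41 are lowest there.

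The comparison of estradiol with DMSO at 6 h keeps the line and the time the same. Genes for photosynthesis in leaf mesophyll had a median of -0.78 with estradiol (percentile 0 among 10000 random lists of matched expression), with 4 of 16 measured members at least 2-fold lower and none at least 2-fold higher. The random lists themselves had a median of -0.22, and reference genes one of -0.24 (percentile 18.6), with 0 of 9 above 0. RCA, encoding rubisco activase, was at 2.28 with estradiol and 3.29 with DMSO, LHCA2 at 2.97 and 4.07, and LHCA3 at 4.14 and 5.16. Early touch and wound response genes had a median of -0.72 (percentile 0, 3 of 16 at least 2-fold lower), with TCH4 lower (-1.23), ZAT10 at 1.33 against 2.53 and CBF2 at -2.03 against -0.74. Against 0 h these genes had a median of -0.31 at 6 h of estradiol (percentile 0.8) and 0.45 with DMSO (percentile 99.8), so the value against DMSO reflects both arrays. Jasmonate biosynthesis and response genes had a median of -0.32 (percentile 0.4), with JAZ7 at -0.29 against 1.19 and JAZ8 at -0.73 against 0.50. Early auxin response genes had a median of -0.35 (percentile 0.3, no member at least 2-fold apart, and -0.20 and outside the lowest 2.5% under quantile scaling), and the flavonoid and anthocyanin pathway one of 0.27 (percentile 99.0, also no member at least 2-fold apart). Meristem regulators had a median of 0.29 (percentile 98.8), with the stem cell peptide gene CLV3 at 1.03 against 0.56, and none of the 12 measured members was at least 2-fold apart; the list left the top 2.5% under quantile scaling (0.20) and cyclic loess (0.22).

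In this comparison 291 genes were at least 2-fold higher and 466 lower, of 19220. The 5 highest were AT5G46310 (3.32), AT3G26855 (2.81), AT3G19390 (2.74), CRC (2.71) and AT3G46850 (2.60). The last 3 of these were higher on all 4 arrays of slide 1 than on both of slide 2, AT3G19390 and AT3G46850 by at least 2-fold and CRC by less. AT5G46310 (0.08 with estradiol) and AT3G26855 (-1.74) were higher still on the XVE array, at 0.78 and -0.75. Their differences from DMSO are thus not particular to plants with the construct. Under normexp AT3G26855 was at 1.69 and AT3G46850 at 1.54. The 5 lowest, AT1G11340 (-6.87), AT3G22030 (-6.20), AT-HSFA5 (-5.45), AT3G62070 (-4.43) and MYB105 (-4.21), were each read by 1 probe that was bright on both arrays of slide 2 and dimmer on all 4 arrays of slide 1. In the alternative setting nearest 0 AT1G11340 was at -3.73. Without 87 genes at least 2-fold apart between the slides on all 8 pairs of arrays, 71 higher on slide 2 and 16 on slide 1, 275 were higher and 395 lower; this exclusion was chosen after the data were seen and leaves AT3G22030 in. Among the 17995 genes well above background on all 6 arrays 236 were higher and 400 lower, where simulated unchanged arrays gave 297 to 396 higher and 281 to 381 lower. LCR72 was at least 13.5-fold, AT4G24300 at least 8.25-fold and AT5G05657 at least 7.16-fold lower with estradiol, and AT2G27540, AT5G17100 and AT1G05085 were at least 6.41-fold, 6.20-fold and 4.27-fold higher. AT2G27540 and AT1G05085 also lay higher on all 4 arrays of slide 1 than on both of slide 2, and AT4G24300 lower. LCR72 and AT5G05657 were higher with DMSO than on every other array, the 0 h array included. AT5G17100 was higher still on the XVE array, at -1.36 against -1.93 at 6 h of estradiol. With normexp the counts were 126 and 270, and without the filter on dim probes 894 and 880.

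Set against plants with XVE alone, with estradiol and 6 h the same, the AMY3C-EY array had photosynthesis genes lower by a median of -1.64 (percentile 0), with 12 of 16 at least 2-fold lower. On the XVE array these genes were themselves above 0 h, by a median of 1.11, with 10 of 16 at least 2-fold higher. RCA was at 2.28 against 4.72, LHCA3 at 4.14 against 6.47 and LHCB3 at 3.48 against 5.60. Touch and wound genes had a median of -0.91 (7 of 16 at least 2-fold lower), with WRKY33 at 0.57 against 2.36, and jasmonate genes one of -0.52 (4 of 21 lower). The touch and wound genes on the XVE array were themselves above 0 h by a median of 0.54 (percentile 99.8). Flavonoid genes had a median of 0.76 (percentile 100, 2 of 10 at least 2-fold higher), with DFR, encoding dihydroflavonol reductase, at 1.88 against 0.28. Abscisic acid and water stress genes had a median of 0.36 (percentile 98.7, and 0.23 and outside the top 2.5% under normexp), with RD29A at 0.65 against -0.92. The reference gene list had a median of -0.36 (percentile 3.8), with UBC9 at 0.12 against 1.19, and epidermis and trichome genes one of 0.38 (percentile 97.9, and 0.34 and outside the top 2.5% under cyclic loess). Starch and sugar metabolism genes had a median of -0.37 (percentile 0.4) and evening clock genes one of 0.42 (percentile 98.2). The ethylene median was -0.44 (percentile 0.9, and -0.33 and outside the lowest 2.5% under cyclic loess).

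The array with XVE alone was the dimmest of the 6, and 687 genes were at least 2-fold higher and 970 lower than on it, of 18584. AT2G12935 (4.01), CRC (3.81), AT3G19390 (3.58), AT1G10300 (3.47) and SLAH1, an anion channel homologue gene (9.85-fold), were highest. All of them were higher on all 4 arrays of slide 1 than on both of slide 2, CRC by less than 2-fold and the others by at least 2-fold. Under normexp CRC was at 2.52, AT3G19390 at 1.76, AT1G10300 at 2.01 and SLAH1 at 1.99. AT1G11340 (-7.89), AT3G22030 (-6.52), AT-HSFA5 (-6.38), AT5G18600 (-4.93) and MYB105 (-4.77) were lowest, and all of them were at least 2-fold higher on both arrays of slide 2 than on all 4 of slide 1. AT2G02440, AT3G22421 and GLYI7 were at least 10.8-fold, 9.50-fold and 7.95-fold higher, and AT1G07120, CYP705A6 and AT4G32580 at least 9.07-fold, 6.57-fold and 6.46-fold lower. AT2G02440 and AT3G22421 also lay higher on all 4 arrays of slide 1 than on both of slide 2. AT1G07120 and CYP705A6 lay lower on slide 1 in the same way. With normexp 313 were higher and 753 lower, 29.4% of these genes being higher against 41.5% on the main scale, and without the filter on dim probes 1409 and 4079 were.

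No plants brushed with solvent, and none with XVE alone, were sampled at 1 h or 3 h. Differences from untreated plants at those times therefore combine estradiol, the construct, brushing and time. In the time course, jasmonate genes stood out 1 h after estradiol. Their median was 1.76 above 0 h (percentile 100), with 16 of 21 at least 2-fold higher and none lower. AOC2, an allene oxide cyclase gene of jasmonate synthesis, was at 0.04 against -4.00 at 0 h, AOS at 3.62 against 0.92, JAZ9 at 4.59 against 1.91 and the jasmonate oxidase gene CYP94C1 at least 96.7-fold higher. Abscisic acid and water stress genes had a median of 1.03 (7 of 13 at least 2-fold higher), with RD20 at 2.69 against -1.27 and KIN2 higher by 3.49. Xenobiotic detoxification genes had a median of 0.63 (percentile 99.9, 6 of 12 higher and 1 lower), with the glutathione transferase gene GSTU5 at 3.98 against 2.01. DNA replication and S-phase histone genes had a median of -0.84 (percentile 0, 4 of 18 at least 2-fold lower), with MCM2 at -2.29 against -1.06, and mitotic genes one of -0.55 (percentile 0.3), with CYCB1;1 at -3.14 against -1.95. The sugar-starvation genes DIN6 (0.08 against -2.90) and DIN1 (-0.02 against -3.11) were higher as well.

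The 10 genes farthest above 0 h at 1 h were RAP2.6, an ethylene response factor family gene (6.31), the chitinase family gene AT2G43620 (6.03), the jasmonate-induced oxygenase gene AT5G05600 (5.73), the dehydrin gene LTI30 (5.43), AT1G30720 (5.33), AT3G23550 (5.16), AT1G51820 (4.96), the peroxidase gene AT5G64120 (4.58), AT2G22880 (4.47) and FAMT (4.39). AT2G38240 and the ABR1 transcription factor gene, dim at 0 h, were at least 156.9-fold and 60.3-fold higher. The 10 farthest below were AT1G57690 (-3.78), AT4G26030 (-3.71), AT3G42786 (-3.16), CSLG2 (-3.03), AT1G44941 (-2.92), AT4G14280 (-2.87), AT3G11380 (-2.74), AT1G54840 (-2.73), AT4G17616 (-2.72) and AT2G35345 (-2.71). Apart from AT3G11380 and AT4G17616, these were also at least 2-fold lower on the XVE array than at 0 h. AT1G57690, for example, was at -1.35 at 1 h and -1.20 on the XVE array, against 2.43 at 0 h. The 1 h and XVE arrays had the lowest 75th percentiles of signal, 481.8 and 341.6. Under normexp FAMT was at 2.59 and AT1G51820 at 3.52, and without the filter on dim probes CSLG2 was at -1.38. The level of FAMT at 0 h, -4.62, lay below the lowest signal well above background on that array, -4.34. AT2G16505, MYB11 and LBD28 were at least 6.65-fold, 6.01-fold and 5.59-fold lower. Of 18552 genes, 1171 were at least 2-fold higher and 1183 lower, and 242 and 73 passed 4-fold. Cyclic loess gave 1393 and 906 (60.6% higher, against 49.7%), normexp 621 and 519, and no filter on dim probes 1840 and 1952.

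At 3 h the jasmonate median was 1.22 (percentile 100, 12 of 21 at least 2-fold higher) and that of abscisic acid and water stress genes 0.88 (6 of 13 higher). The late jasmonate gene VSP1 was at 1.27, against -0.49 at 1 h and -0.70 at 0 h. S-phase genes had a median of -0.74 (percentile 0, 4 of 18 lower), with H4b at 0.02 against 1.51 at 0 h, and cytokinin response and turnover genes one of -0.40 (percentile 0.4, and -0.32 and outside the lowest 2.5% under normexp), with CKX3 at -2.08 against -1.06. The morning and evening clock lists had medians of -0.35 and 0.00. The 10 highest genes were AT2G43620 (6.01), RAP2.6 (4.48), LTI30 (3.92), AT5G05600 (3.92), AT5G61890 (3.57), KIN2 (3.52), FAMT (3.51), CORI3 (3.46), AOC2 (3.45) and the β-glucosidase gene BGLU25 (3.17). Under normexp AT5G61890 was at 1.07, FAMT at 1.57 and AOC2 at 2.06. The levels of AT5G61890 (-5.45) and FAMT (-4.62) at 0 h lay below the lowest signal well above background on that array, -4.34. NATA1, an acetyltransferase gene, and the ribonuclease gene RNS1 were at least 54.5-fold and 46.5-fold higher, and AT2G38240 at least 29.6-fold.

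The 10 lowest genes at 3 h were CSLG2 (-3.91), ESE1 (-3.37), PP2-B7 (-3.15), AT2G27540 (-3.08), AT4G11590 (-2.96), AT1G66800 (-2.80), AT2G14160 (-2.73), the signal peptide gene CHAL (-2.66), AT3G23190 (-2.63) and Tic20-IV (-2.58). With only the brightest probe AT1G66800 was at -0.50, less than 2-fold lower, and under normexp Tic20-IV was at -1.28, CHAL at -1.69 and PP2-B7 at -1.93. In the alternative setting nearest 0 CSLG2 was at -2.48. MYB11, LBD28 and AT1G26798 were at least 14.0-fold, 13.03-fold and 11.99-fold lower. In total 457 genes were at least 2-fold higher and 961 lower (32.2% higher), of 19235. Quantile scaling gave 606 and 728 (45.4% higher) and normexp 174 and 957 (15.4% higher), and without the filter on dim probes 913 were higher and 3911 lower.

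By 6 h the clock genes were far from their levels at 0 h. Evening-phased genes had a median of 2.75 (percentile 100, 7 of 8 at least 2-fold higher) and morning-phased genes one of -1.95 (percentile 0, 7 of 8 at least 2-fold lower). PRR5 was at 1.54 against -2.08, PRR3 at 0.34 against -4.20, CCA1 at -3.98 against -1.18 and LHY at -1.18 against 1.18. Jasmonate genes had a median of 0.66 (8 of 21 higher), abscisic acid and water stress genes one of 0.96 (6 of 13 higher), flavonoid genes one of -0.91 (percentile 0, 5 of 11 lower) and photosynthesis genes one of -0.53 (percentile 0, 2 of 16 lower). AT2G43620 (6.40), AT1G56300 (4.71), NAC019 (4.57), PRR3 (4.55) and GRP7, an RNA-binding protein gene of the clock (4.02), were highest, and COL2 (-4.11), AT2G27402 (-3.02), CSLG2 (-2.95), AT4G11590 (-2.92) and AT3G12320 (-2.85) lowest. Under normexp PRR3 was at 2.90 and AT4G11590 at -1.67, and without the filter on dim probes CSLG2 was at -1.43. NATA1 was at least 49.5-fold, RNS1 at least 23.61-fold and COR27 at least 17.2-fold higher, and MYB11, LBD28 and ESE1 at least 9.17-fold, 8.54-fold and 8.39-fold lower. Of 19181 genes, 500 were at least 2-fold higher and 545 lower. Normexp gave 243 and 219, and no filter on dim probes 992 and 1254.

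The DMSO array against 0 h shows what 6 h and brushing with solvent came with in the same line, across slides. Its clock medians were 2.56 (evening) and -2.09 (morning), its jasmonate median 1.11 (11 of 21 higher) and its abscisic acid and water stress median 0.80 (6 of 13 higher). On the XVE array the jasmonate median against 0 h was 1.34, with 16 of 21 higher. VSP2 was at 3.19 with DMSO and 0.57 at 0 h, and AOC2 at -0.46 and -4.00. Touch and wound genes had a median of 0.45 (percentile 99.8), cytokinin genes one of -0.52 (percentile 0) and flavonoid genes one of -1.37 (percentile 0, 6 of 11 lower), with F3H at -1.20 against 0.44. AT2G43620 (6.39), AT1G11340 (6.35), AT3G22030 (6.05), NAC019 (5.07) and AT1G56300 (4.45) were highest, of which AT1G11340 (3.58 without the filter on dim probes) and AT3G22030 were bright on both arrays of slide 2. AT3G46850 (-3.93), COL2 (-3.58), AT3G50925 (-3.51), AT2G02440 (-3.49) and AT4G35210 (-3.42) were lowest, and all but COL2 were at least 2-fold higher on all 4 arrays of slide 1 than on both of slide 2. NATA1, RNS1 and JRG21 were at least 70.3-fold, 29.97-fold and 28.3-fold higher, and AT2G27540, AT2G16505 and KCS15 at least 15.2-fold, 7.81-fold and 6.83-fold lower. AT2G27540, AT2G16505 and KCS15 also lay higher on all 4 arrays of slide 1 than on both of slide 2. In total 866 genes were at least 2-fold higher and 763 lower, of 18768; normexp gave 500 and 413, and no filter on dim probes 1395 and 1743.

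Of 495 genes at least 2-fold higher at 6 h of estradiol than at 0 h, 347 (70.1%) were also at least 2-fold higher with DMSO, where independent lists would share 23.5. Of 407 lower, 169 (41.5%) were shared, against 14.4. At 3 h the shared counts were 270 of 446 higher genes and 246 of 736 lower (independent lists: 21.1 and 26.1), and at 1 h 256 of 1129 and 177 of 1128 (53.4 and 39.7). Both sides use the same 0 h array, and by that alone simulated unchanged arrays shared a mean of 92.7 higher and 92.3 lower genes at 6 h, 91.4 and 91.2 at 3 h, and 91.6 and 92.5 at 1 h. The simulated lists were of another length than the observed ones, a mean of 336.8 higher genes at 1 h for example, so the shares do not compare directly. With 1 array at 0 h the shared control could not be split, and part of the sharing may come from it at each time.

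The pair of 6 h controls, on 1 slide, differed in line and in estradiol. Photosynthesis genes were higher on the XVE array by a median of 0.95 (percentile 100, 7 of 16 at least 2-fold higher), with LHCB2.2 at 4.80 against 3.48 with DMSO. Flavonoid genes had a median of -0.68 (percentile 0), with LDOX at -6.02, not well above background, against -3.72, and abscisic acid and water stress genes one of -0.44 (percentile 0.2). Morning clock genes had a median of 0.48 (percentile 99.5), ethylene genes one of 0.33 (percentile 99.6, and 0.25 and outside the top 2.5% under normexp) and jasmonate genes one of 0.11. AT5G46310 (4.03), AT3G26855 (3.81), AT5G63270 (3.23), AT2G31210 (3.12) and UGT72E3 (3.09) were highest, and AT5G08505 (-4.05), AT4G20000 (-3.85), AT1G57690 (-3.67), AT4G26030 (-3.41) and AT1G54840 (-3.32) lowest. The last 3 were also among the 10 lowest at 1 h. Without the filter on dim probes UGT72E3 was at 1.78, and under normexp AT3G26855 was at 2.64. AT5G17100, AT5G38390 and AT3G33494 were at least 9.18-fold, 5.85-fold and 5.74-fold higher, and LCR72, CAX3 and GLYI7 at least 6.55-fold, 4.68-fold and 4.04-fold lower. Of 18483 genes, 372 were at least 2-fold higher and 381 lower. Normexp gave 312 and 217, and no filter on dim probes 869 and 840.

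**Figure D2:**
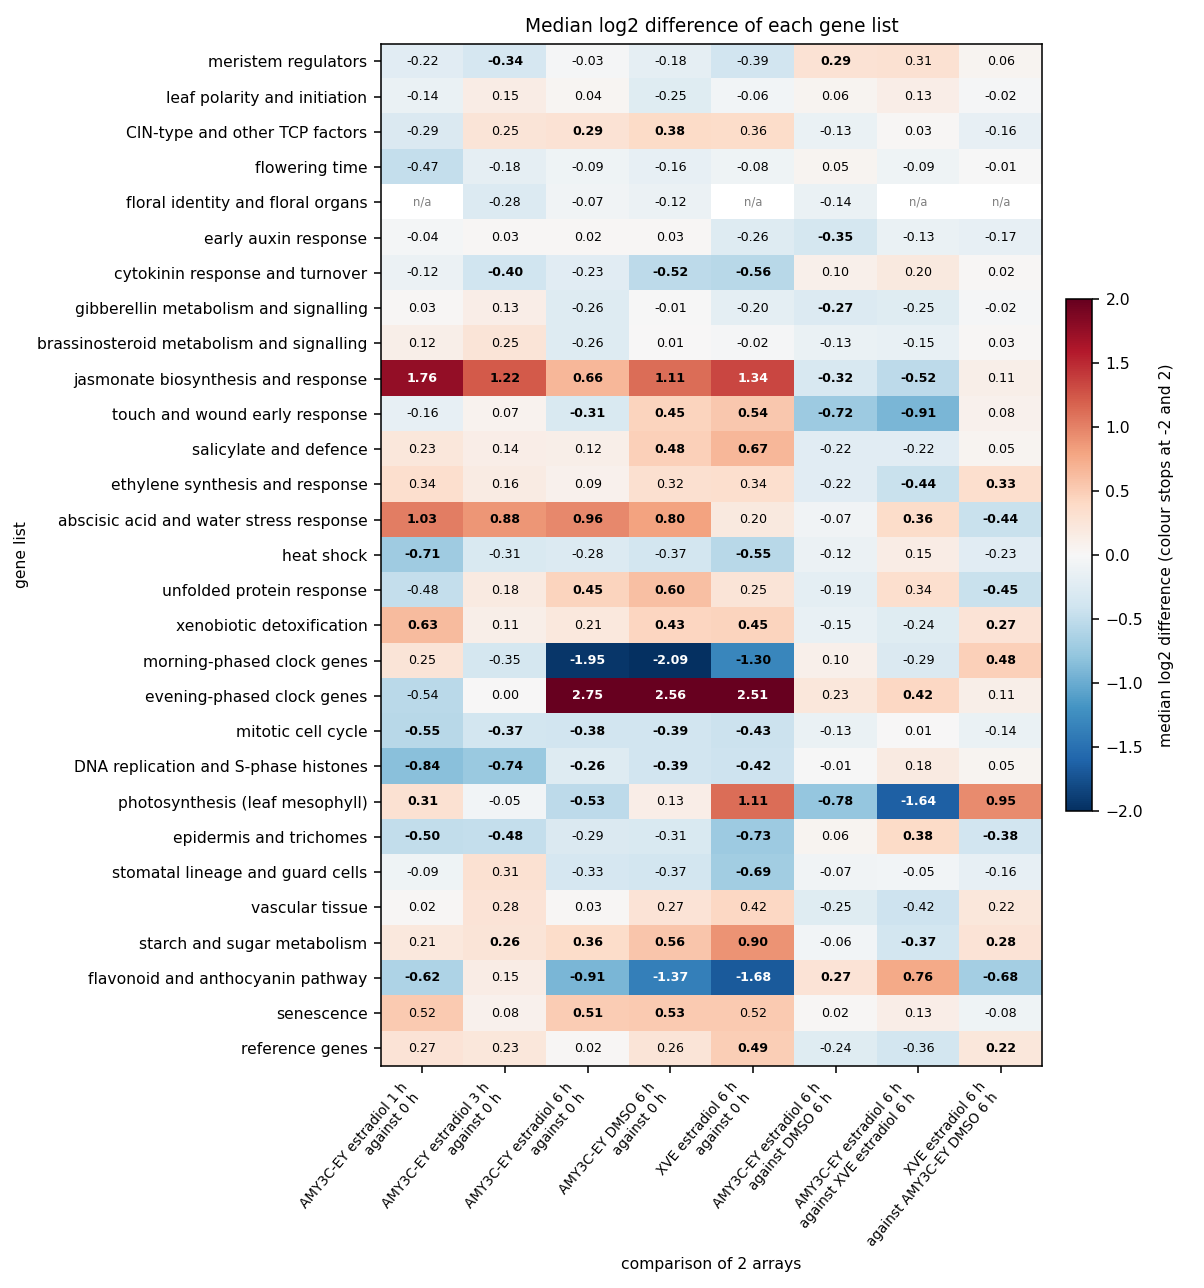
Median log2 difference of each of 29 gene lists (top to bottom) in 8 comparisons of 2 arrays (left to right), printed in each cell and shown by colour, with bold for medians within the lowest or highest 2.5% of random lists and n/a where fewer than 5 members were measured. The evening clock list is at 2.75, 2.56 and 2.51 on the 3 arrays of 6 h against 0 h, and the jasmonate list at 1.76 at 1 h.

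**Figure D3:**
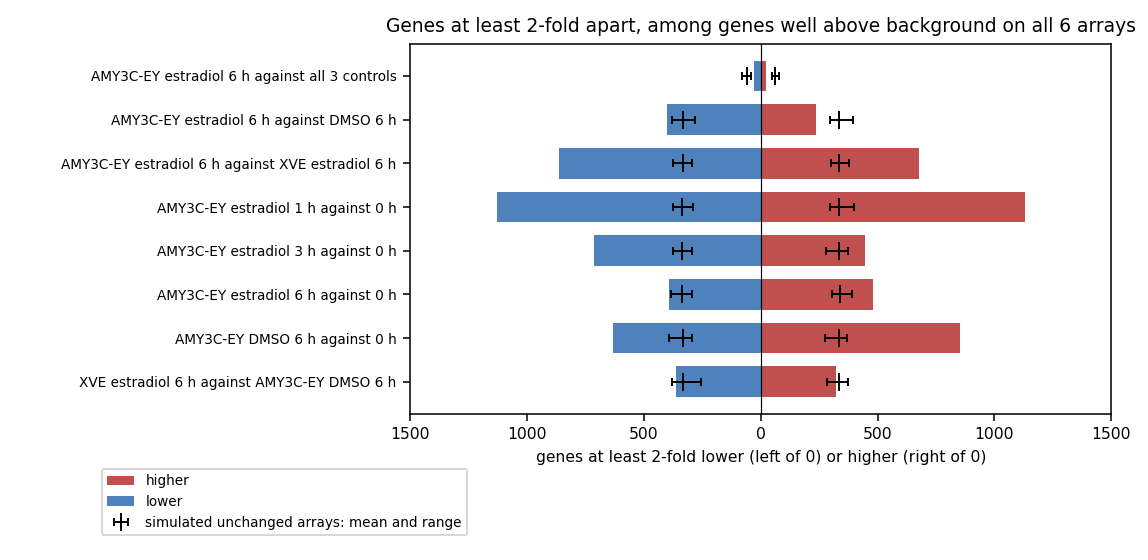
Number of genes at least 2-fold lower (bars to the left) or higher (bars to the right) in each comparison, among 17995 genes well above background on all 6 arrays, with the mean (tick) and range (whiskers) of 100 simulations of unchanged arrays. The bars against all 3 controls end at 31 and 24 genes, below the simulated ranges of 44 to 82 and 46 to 80, and the longest, at 1 h, at 1128 and 1129; the last comparison supplied the simulated spread.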

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

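The tests of tissue share, of time of day and of a construct transcript below were chosen after the results were seen. Among 3841 probes without a locus name, which enter no comparison above, 17 were at least 2-fold higher at 6 h of estradiol than on all 3 controls, and 17 at least 2-fold lower. The farthest of them, A_84_P554551, was at 0.89 at 6 h, against -1.27 at 0 h, -1.24 with DMSO and -1.99 on the XVE array, a smallest difference of 2.13, and it was at -1.22 at 1 h and -0.42 at 3 h.

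A set of 87 genes parted the 2 slides by at least 2-fold on all 8 pairs of arrays, 71 of them higher on slide 2, and 19 of those by at least 4-fold; AT1G11340 (6.35), AT-HSFA5 (4.44), AT3G62070 (3.90), MYB105 (3.68) and MPK6 (2.72) are examples. Any other split of 2 arrays from 4 gave at most 34 genes. Scaling of arrays of unequal brightness is argued against, since 83 genes remained in number after quantile scaling and 89 after cyclic loess. Under the normexp background correction the number was 63. A genome segment that differs between the plants is argued against too, with 0 neighbouring pairs within 5 measured genes, where random draws gave 0 to 8. Counted by probe, 139 named probes parted the slides, 63 of them of genes with other probes. The 93 other probes, which did not part the slides themselves, had a median slide difference of 0.20 against 1.98, a ratio of 0.10. Leaving out other probes that part the slides lowers this ratio. For probes apart between 6 h and the early arrays, treated alike, it was 0.63. Single probes that hybridised differently on the 2 slides are thus a candidate explanation for such genes. Most of the 87 genes, and the examples above, were read by 1 probe, so this check does not reach them.

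Photosynthesis genes were lower at 6 h of estradiol than on each control, by medians of -0.53 (0 h), -0.78 (DMSO) and -1.64 (XVE), while against 0 h they were at 0.31 at 1 h (percentile 100) and at -0.05 at 3 h, the latter 0.34 under quantile scaling and 0.23 under cyclic loess. Intensity-dependent scaling as the whole cause is argued against, since after cyclic loess the median nearest 0 was still -0.35. A smaller share of leaf tissue in that sample may also account for it: vascular genes had medians of 0.03, -0.25 and -0.42, guard cell genes of -0.33, -0.07 and -0.05, and meristem genes, which a smaller leaf share would raise, of -0.03, 0.29 and 0.31 against 0 h, DMSO and XVE. The rule set for this check counted a vascular or guard cell median above 0 against any control as evidence against a smaller leaf share. The highest vascular median, 0.03, met that rule. It is too close to 0 for these 8 genes to decide, given a spread of 0.17 among random lists. The full pattern of a smaller share was not seen either, with guard cell medians of -0.07 and -0.05 and a meristem median of -0.03. Tissue share and an effect of the induced construct therefore cannot be told apart. With the DMSO and XVE arrays on another slide, the slide stays open as well for those values. The XVE array itself lay above 0 h by a median of 1.11, so the value against XVE reflects both arrays.

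AMY3 was higher at 6 h of estradiol than on all 3 controls. A shared time of day alone is argued against, because the DMSO and XVE arrays, taken at the same interval after treatment, lay at least 1.35 below. That is beyond the spread of 0.38 between those arrays. Equal intervals do not fix the hour of harvest, so a difference in time of day between these arrays is not excluded. Evening clock genes at 6 h of estradiol had medians of 0.23 against DMSO (percentile 94.9) and 0.42 against XVE (percentile 98.2). The morning medians were 0.10 (percentile 72.9) and -0.29 (percentile 10.1). A transcript made from the construct and read by the AMY3 probe is a candidate explanation from the name alone, since the labels do not say what AMY3C-EY encodes. The DMSO array was 0.05 above the XVE array, within the spread, and the level was higher at each later time, yet an effect on the plant's own gene would look alike, so the values do not decide. Slide together with time of day, and chance, stay open. In unchanged simulated arrays a mean of 21.8 of 17995 genes reached this difference, and 2.2 of the 900 at similar mean expression. Observed were 8 genes. The simulated spread includes any effect of line and estradiol, so these numbers cannot settle chance for AMY3.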

How the results depend on the processing

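All alternative settings were planned except the exclusion of genes that part the slides, which was chosen after the data were seen. The 16 counts of genes at least 2-fold apart stayed within 1.5 times their main value under quantile scaling, cyclic loess, the authors' table, the brightest probe and the filter on all 6 arrays, as did the 8 counts rerun without the genes that part the slides. Under the normexp background correction 13 of 16 counts moved. Higher and lower, they were 12 and 9 against all 3 controls, 126 and 270 against DMSO, 621 and 519 at 1 h, 243 and 219 at 6 h against 0 h, and 500 and 413 for DMSO against 0 h. Only the higher count moved against XVE (313) and at 3 h (174), and only the lower for XVE against DMSO (217). No filter on dim probes moved all 16: 99 and 142 against all 3 controls, 894 and 880 against DMSO, 1409 and 4079 against XVE, 1840 and 1952 at 1 h, 913 and 3911 at 3 h, 992 and 1254 at 6 h against 0 h, 1395 and 1743 for DMSO against 0 h, and 869 and 840 for XVE against DMSO; this setting adds genes with signals near background. Leaving out each control in turn gave 53 to 126 higher and 68 to 238 lower genes. Fewer arrays must then be passed, which raises the counts in each case. The largest counts, 126 and 238 without the 0 h array, are against arrays of slide 2 only. The normexp setting adds 50 to each corrected signal, which by itself compresses log2 signals of dim genes, more so on dim arrays. The median processed signal was 80.6 on the XVE array and 323.4 at 3 h. How much of the moved counts this offset accounts for was not tested. The median difference of all genes was -0.19 under normexp and -0.05 in the main setting at 3 h against 0 h, and -0.14 without the filter and -0.02 in the main setting for DMSO against 0 h, so differences under these are relative to such medians. All 12 higher and 9 lower genes that normexp left against all 3 controls were among the main ones. Of 88 list medians within the lowest or highest 2.5% of random lists, 82 stayed there under quantile scaling, 79 under cyclic loess and 74 under normexp, and none changed sign under these 3. Of all 228 list medians, normexp moved 71, the brightest probe 36, no filter 22, quantile scaling 15 and cyclic loess 8 by more than the spread of random lists, and the filter on all 6 arrays, which gave fewer of them, moved 5. Of the 120 values of single named genes, normexp moved 79 by more than 0.38, the spread between the XVE and DMSO arrays, no filter 9, the brightest probe 5, cyclic loess 3 and quantile scaling 2. SULTR3;2 and AT5G56880 were no longer above all 3 controls under normexp (0.00 each, as the differences from the controls then had unlike signs). Under the brightest probe PUB22 was at -0.24, SULTR3;2 at 0.18 and AT1G66800 at 3 h at -0.50. Signal over background limits the XVE array most. No paired analysis was possible because each group is 1 array.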

Other observations

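No explanation is offered for the following values, and none was tested. Of 18 starch and sugar metabolism genes, 5 were at least 2-fold higher than at 0 h and 1 lower at 6 h of estradiol, 8 and 1 on the XVE array and 6 and 1 with DMSO. ISA3, a debranching enzyme gene, was at -2.47 at 0 h, and at -0.25 with estradiol, -0.41 on the XVE array and -0.30 with DMSO. The starch phosphorylating dikinase genes GWD1 (0.43 at 0 h, then 2.26, 2.74 and 2.34 in the same order) and PWD (-1.40, then -0.07, -0.12 and -0.22) lay higher too. GBSS1, the granule-bound starch synthase gene, was lower, at 0.94 at 0 h and -1.34, -1.54 and -1.15 later. The list median was 0.36 with estradiol, 0.90 on the XVE array and 0.56 with DMSO (percentile 100 each), 0.21 at 1 h and 0.26 at 3 h, the last 0.01 under normexp. Set directly against the XVE array, the list at 6 h of estradiol had a median of -0.37 (percentile 0.4).

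Other lists differed from 0 h on several arrays. Unfolded protein response genes had medians of -0.48 at 1 h, 0.45 at 6 h (percentile 100) and 0.60 with DMSO (percentile 99.7), with the chaperone gene BIP2 at -0.64, 0.57 and 0.73 against 0.28 at 0 h. Salicylate and defence genes had medians of 0.48 with DMSO (percentile 99.4) and 0.67 on the XVE array (percentile 99.8), with PAD4 at -2.14 and -1.56 against -3.12 at 0 h, and 0.12 at 6 h of estradiol. Heat shock genes had a median of -0.71 at 1 h (percentile 0.7, and -0.51 and outside the lowest 2.5% under quantile scaling), with HSFA7A at -0.25 against 1.18. Senescence genes had a median of 0.51 at 6 h (percentile 99.6), with ORE1 at -1.39 against -3.73, over 6 measured members.

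Epidermis and trichome genes had medians of -0.50 at 1 h, -0.48 at 3 h and -0.73 on the XVE array against 0 h, the first -0.43 under quantile scaling and -0.41 under cyclic loess and then outside the lowest 2.5%, with GL2 at -1.04 at 1 h and -1.20 on the XVE array against 0.10. Guard cell genes had a median of -0.69 on the XVE array against 0 h (percentile 2.1, 6 members), with TMM at -1.03 against 0.26. TCP factors had medians of 0.29 at 6 h and 0.38 with DMSO (percentile 98.6 and 98.3), and 0.16 and 0.21 under normexp, outside the top 2.5%, with TCP17 at 0.47 and 1.15 against -0.84. Flowering time genes had a median of -0.47 at 1 h (percentile 2.8), with AGL24 at 1.73 against 3.14. At 6 h of estradiol against DMSO the medians were 0.06 for leaf polarity genes, -0.27 for gibberellin, -0.13 for brassinosteroid, -0.22 for ethylene, -0.14 for floral identity and 0.02 for senescence genes. The gibberellin median was at percentile 2.1. It left the lowest 2.5% under quantile scaling (-0.24) and cyclic loess (-0.25). Of the reference genes, PP2AA3 lay between 0.90 and 1.19 on the 6 arrays, while ACT8 was at 1.14 on the XVE array and between -0.16 and 0.31 on the rest.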
